A study of Mus musculus with 24 samples.

How the data were processed

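Total RNA of sorted CD4 T cells from female C57BL/6 mice aged 6 or 7 weeks was labelled with Cy3 and hybridized to 24 Agilent mouse arrays with 4 arrays per slide. The 6 groups of 4 were WT and CKO naive unstimulated, naive stimulated and Treg cells. Naive cells were sorted as CD4+ CD25- and Treg as CD4+ CD25+ among other markers, per the labels. CKO mice lack Trim28 in T cells. Stimulated cells had 13 h of plate-bound anti-CD3 and anti-CD28. The deposited scanner files give each spot's processed signal as an intensity, which per the file headers was background subtracted and detrended within the array with low values replaced by surrogates (Feature Extraction 9.5 by the authors' notes). The authors' set of normalized values, also an intensity on a linear scale, had the same distribution in every column, as quantile normalization gives, and followed the processed signal of its own array in rank. It served as an alternative.

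The processed signal was put on the log2 scale and the array's 75th percentile was subtracted. Spots that the scanner software marked as outliers were left out and spots of a probe were averaged. A probe was kept when it was well above background on at least 3 of the 4 arrays of at least 1 group, which kept 25198 of 41174 probes, and a gene was represented by its brightest kept probe, which gave 16489 genes. Group means were fitted to all 24 arrays with limma 3.58.1 in R 4.3.3 (with jsonlite 2.0.0 and version 1.17.8 of data.table), and 9 contrasts were tested 2-sided with moderated statistics and Benjamini-Hochberg adjusted p under 0.05. These were CKO against WT in 3 states, stimulated against unstimulated and Treg against naive unstimulated in each genotype, and 2 interactions. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

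The 25 gene lists fell into several kinds. Those on T cells were T cell activation, effector cytokines, Th17 program, Treg signature, naive and quiescence, effector and memory CD4, IL-2 and STAT5 targets, and inhibitory receptors and anergy. Those on processes were TGF-beta pathway, cell cycle, ribosome biogenesis, glycolysis, cholesterol synthesis, interferon-stimulated genes, p53 targets and stress response. Those on silencing were KRAB zinc fingers, imprinted genes, germline genes, and heterochromatin and TRIM28 partners. The rest were markers of B cells, myeloid and dendritic cells, CD8, NK and unconventional T cells, erythroid cells and platelets, and stromal and epithelial cells. Each was tested with camera at a preset correlation of 0.01 and again with an estimated one, adjusted over the 25 lists of a contrast, and fry was run beside it. With an estimated correlation 4 calls held: KRAB zinc fingers in CKO against WT Treg, the Treg signature in Treg against naive cells of each genotype, and inhibitory receptors in Treg against naive WT cells. Members past the test were counted over all genes and adjusted over the list alone. Some genes sit in more than 1 list.

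The groups, contrasts, lists, alternatives and rule for named genes were set before the data were examined. The rule took fixed genes, among them Trim28, Il2, Tgfb3, Foxp3, Il2ra, Ifng, Il17a, Cd4 and Cd8a, and a further fixed gene is not reported here. It added the 10 largest rises and falls among called genes that were well above background on at least 3 arrays of both groups and whose groups did not overlap, leaving out provisional names. It also took up to 5 genes per direction that only 1 of the groups showed above background, and up to 4 members of each list. A gene not well above background on any array of a group has no fitted fold here: it is given a bound. The mean of the bright group is set against the mean of the dim group, with each dim array at the higher of the gene's own signal and the lowest signal that array called well above background. List medians are also given with such members so limited in the dim group, written as with bounds, and with a signal floor where that moved them by over 1.5 times. That floor put every signal below a log2 value of -2.69 at it, the highest over the arrays of their lowest signals called well above background.

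The 75th percentile of the signal was 154 to 372 on naive arrays, 53.9 to 200.2 on WT Treg arrays and 31.3 to 116 on CKO Treg arrays, and the share of probes well above background from 43.0% to 61.2%. Replicates correlated at 0.961 to 0.993 across genes. The median SE of a log2 fold change was 0.22. In a test on simulated data with 200 changes planted, a log2 change of 1 was recovered for 65.7% of genes in the unstimulated, 55.2% in the stimulated and 56.7% in the Treg comparison. A change of 2 was recovered for 89.6%, 92.5% and 86.6%, and a change of 0.5 for 15.2%, 10.6% and 15.2%. There were 7, 4 and 2 false calls. Each rate rests on 66 or 67 planted genes, so the spread between comparisons does not show unequal sensitivity. Far fewer changes were planted than the 3088, 3964 and 710 genes called on the real arrays. These rates describe the simulation only, and sensitivity and false calls on the real arrays may differ.

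The arrays came on 6 slides, and same-numbered CKO and WT arrays of a state shared a slide. Arrays of different groups on the same slide had a median correlation of residuals of 0.216 (36 pairs), against -0.0244 on different slides (204 pairs). The labels do not say that numbers pair samples. Same-numbered arrays correlated above 0.1 in all 4 replicates for CKO Treg against CKO naive unstimulated cells alone (0.469, 0.453, 0.366 and 0.490), where a block on the number gave 5387 genes against 4666 without it. Other comparisons within a genotype came near this. Values were -0.163, 0.545, 0.494 and 0.346 for stimulation in WT and 0.226, 0.379, 0.244 and 0.0904 in CKO. For WT Treg against naive unstimulated cells they were 0.0588, 0.466, 0.348 and 0.273. Between genotypes, CKO and WT Treg came near it too (0.234, 0.457, 0.247 and 0.0831), while both comparisons of naive CKO and WT cells had negative values among them. Replicate 1 was aged 7 weeks for CKO Treg and for stimulated cells of both genotypes, but 6 weeks for unstimulated cells of both. Number 1 therefore does not mark mice of the same age across these groups. For the other numbers a link within a genotype is possible, and the main fit did not model it.

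Alternatives, tried one at a time, were quantile normalization, normexp background correction with quantile normalization, the authors' normalized values, a percentile over probes well above background on all 24 arrays (the brightest shared probes), no filter on dim probes, a stricter one and a floor on the signal. Others were the mean of a gene's kept probes, only the compared arrays, robust and trended variances, array weights, replicate number or slide as a block, age as a covariate and leaving out each array in turn.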

Results

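CD4 T cells from mice lacking Trim28 in T cells (conditional knockout, CKO) were compared with wild-type (WT) cells in 3 states: naive unstimulated, naive stimulated for 13 h with plate-bound anti-CD3 and anti-CD28, and regulatory T cells (Treg), with n = 4 arrays per group. Trim28 encodes a corepressor that KRAB zinc finger proteins recruit to chromatin. Its mRNA was 2.85-fold lower in CKO naive unstimulated cells (log2 fold change -1.51 ± 0.17, SE), 6.43-fold lower in stimulated cells (-2.68 ± 0.17) and 2.96-fold lower in Treg (-1.57 ± 0.17). In each state all 4 CKO arrays lay below all 4 WT arrays. The limma adjusted p-values were 4.45e-06, 8.97e-10 and 1.95e-06. One probe reads Trim28, and whether it lies in the deleted part of the gene is not known.

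Tgfb3, which encodes a TGF-beta ligand, rose in all 3 states: 8.33-fold in unstimulated (3.06 ± 0.29), 9.26-fold in stimulated (3.21 ± 0.29) and 7.64-fold in Treg (2.93 ± 0.29). In WT stimulated cells it was well above background on only 2 of 4 arrays, at a mean log2 value of -4.67. The size of the fold in stimulated cells is therefore uncertain. Foxp3, the lineage factor of Treg, was 1.94-fold higher in CKO naive unstimulated cells (0.96 ± 0.20, adjusted p = 0.00356) and 5.46-fold higher in stimulated cells (2.45 ± 0.20, adjusted p = 5.30e-08). Its level in CKO stimulated cells, a mean log2 value of -1.31 ± 0.26 (SD), stayed far below that of CKO Treg, 3.34 ± 0.18. In Treg the Foxp3 difference was 0.08 ± 0.20, adjusted p = 0.926. The call in unstimulated cells was lost after normexp background correction (adjusted p = 0.0794). Cd4, the coreceptor that defined the sort, differed by -0.11 ± 0.15, adjusted p = 0.633 in unstimulated cells, -0.04 ± 0.15, adjusted p = 0.876 in stimulated cells and 0.04 ± 0.15, adjusted p = 0.961 in Treg. Il17a, the Th17 cytokine, was not well above background on any of the 24 arrays.

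**Figure D1:**
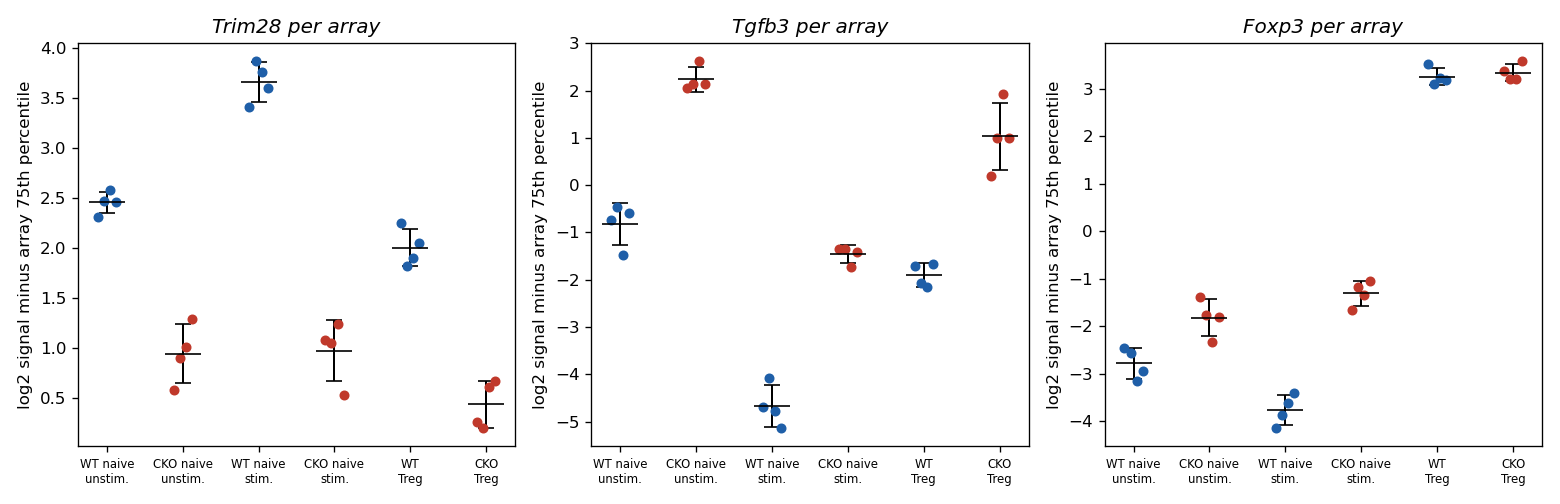
Log2 intensity, relative to the 75th percentile of each array, of Trim28, Tgfb3 and Foxp3 on each of the 24 arrays, with the mean and SD of each group of 4 (WT blue, CKO red). Trim28 is lower and Tgfb3 higher in CKO arrays of every state, and Foxp3 is higher in CKO naive cells but stays below Treg.

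In naive unstimulated CKO cells Upk1b, a membrane protein of bladder epithelium, was 173-fold higher (7.43 ± 0.45), and Tdrd9, a germline helicase of the piRNA pathway, 106-fold higher (6.72 ± 0.72). F12, which encodes a coagulation factor, rose 43.3-fold (5.43 ± 0.34), Cbr3, a carbonyl reductase, 23.3-fold (4.54 ± 0.62) and Gstt3, a glutathione transferase, 22.7-fold (4.50 ± 0.28). Lix1 rose 55.2-fold, Wfdc2 27.9-fold and Cdr2l 22.6-fold. Cthrc1, a secreted collagen-associated protein, was well above background in CKO only and was at least 16.4-fold higher. Such a bound sets the mean of the bright group against a mean of the other in which each array has the higher of its own value and its lowest signal called well above background.

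The largest falls in these cells included Nacc2, a transcriptional repressor (-3.58 ± 0.33), and Hid1, 8.38-fold lower (-3.07 ± 0.42). Pmepa1, a TGF-beta-induced inhibitor of SMAD signalling, was 6.65-fold lower (-2.73 ± 0.32), Gpr83, a receptor abundant in Treg, 5.69-fold lower (-2.51 ± 0.20) and Rnf43, a ubiquitin ligase that limits Wnt receptors, 4.67-fold lower (-2.22 ± 0.27). Il2ra, the alpha chain of the IL-2 receptor (CD25), was 2.14-fold higher (1.10 ± 0.16, adjusted p = 1.09e-04), a call lost after normexp correction (adjusted p = 0.393). Ifng differed by 0.83 ± 0.40, adjusted p = 0.148. Cd8a, a coreceptor of CD8 T cells, differed by 1.25 ± 0.51, adjusted p = 0.0877. Il2 was not well above background in CKO unstimulated cells.

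Ribosome biogenesis genes fell in unstimulated CKO cells: 14 of 33 members were lower (18 when adjusted over the list alone), among them Dkc1, a pseudouridine synthase (-1.26 ± 0.20), Bysl (-0.94 ± 0.19) and Srm, spermidine synthase (-0.94 ± 0.17). The list median was -0.38 (camera adjusted p = 6.76e-07, adjusted p = 0.527 with an estimated correlation). Of the cholesterol synthesis genes 10 of 22 fell and 1 rose (11 and 1 when adjusted over the list alone), with Sqle, squalene epoxidase, at -1.51 ± 0.29 and a median of -0.49 (camera adjusted p = 5.03e-04, adjusted p = 0.576 with an estimated correlation). Of the inhibitory receptor and anergy genes 5 of 23 rose (8 when adjusted over the list alone), including Ctla4, which competes for B7 ligands (1.56 ± 0.28), and Btla (1.46 ± 0.18), with a median of 0.37, 0.20 with a signal floor (camera adjusted p = 0.00588, adjusted p = 0.249 with an estimated correlation). Among chromatin partners of TRIM28, Trim24, a member of the same TIF1 family, rose (3.16 ± 0.14). Markers of other cells were higher with these groups. B cell markers had a median of 1.13 (camera adjusted p = 0.00164, adjusted p = 0.576 with an estimated correlation) with 2 of 16 members called and 5 at an unadjusted p under 0.05, and limma called none adjusted over the list alone. CD8, NK and unconventional T markers had a median of 1.25, 0.38 with a signal floor (camera adjusted p = 0.00868, adjusted p = 0.576 with an estimated correlation), with 6 of 14 higher and 1 lower (9 and 1 when adjusted over the list alone), a call lost among genes well above background on all 24 arrays (adjusted p = 0.440). In the pairs of CKO and WT arrays on the 4 slides the medians were 2.64, 1.12, 1.01 and -0.27 for B cell markers and 2.03, 1.02, 0.44 and 0.39 for CD8, NK and unconventional T markers. They were -0.29, -0.56, -0.47 and -0.47 for ribosome biogenesis, -0.43, -0.69, -0.40 and -0.39 for cholesterol synthesis and 0.31, 0.16, 0.55 and 0.31 for inhibitory receptors.

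In the Treg signature 6 rose and 2 fell of 22 (7 and 3 when adjusted over the list alone) in unstimulated cells, in T cell activation 4 rose and 2 fell of 25 (7 and 2 when adjusted over the list alone) and in the chromatin partners of TRIM28 5 rose and 2 fell of 28 (5 and 2 when adjusted over the list alone). On the 4 slides the medians were 0.57, 0.29, 0.77 and 0.17, 0.23, 0.13, 0.58 and 0.12 and 0.32, 0.20, 0.24 and -0.07, in that order. Their camera adjusted p-values of 0.0255, 0.0408 and 0.0275 were 0.576, 0.576 and 0.527 with an estimated correlation. The Treg signature call was also lost under several alternatives, among them after quantile normalization (adjusted p = 0.0549) and without WT replicate 3 (adjusted p = 0.0886). T cell activation lost its call with only the compared arrays fitted (adjusted p = 0.0725) and without WT replicate 2 (adjusted p = 0.0592), CKO replicate 3 (0.0742) or CKO replicate 4 (0.119), and the chromatin partners lost theirs with only the compared arrays fitted (adjusted p = 0.0683). In the TGF-beta pathway 4 rose and 4 fell of 21 (5 and 5 when adjusted over the list alone): the median was -0.09 while the mean was 0.19 and the test read up (camera adjusted p = 0.905). Of the imprinted genes 2 rose and 4 fell of 23 (3 and 4 when adjusted over the list alone), and of the p53 targets 1 rose and 3 fell of 24 (1 and 3 when adjusted over the list alone). Neither list passed (camera adjusted p = 0.905 and 0.349). In the glycolysis list 4 of 20 fell (7 when adjusted over the list alone, 1 higher; camera adjusted p = 0.0633), and in the stress response 2 of 24 (1 when adjusted over the list alone; camera adjusted p = 0.140).

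In all, 3088 of 16489 genes differed between CKO and WT unstimulated cells, 1291 higher and 1797 lower (41.8% higher, against 54.9% when arrays were scaled on the brightest shared probes). Some called genes, with groups that did not overlap, were well above background on at least 3 arrays of 1 genotype and on none of the other. Of those with a bound above 1-fold, 73 were higher and 16 lower in CKO. The sign of the difference within each of the 4 slides matched the call for 98.9, 99.7, 99.3 and 82.7% of the 3088 genes. These genes were called from the same arrays, so high agreement follows largely from their selection and is no separate support. The count was 1385 without WT replicate 2, 1563 without WT replicate 3, 1544 without CKO replicate 2 and 1606 without CKO replicate 3. It was 1700 with only the 8 compared arrays fitted, 1801 with no filter on dim probes and 6616 with array weights. The labels do not state whether the arrays come from separate animals, so p-values measure the spread between these samples.

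In stimulated cells without Trim28, cell cycle genes were lower. Of 41 measured members 34 fell (34 when adjusted over the list alone), including Cdk1, the mitotic kinase, 6.15-fold lower (-2.62 ± 0.57), Cdc6, which loads the replicative helicase (-2.20 ± 0.44), and Mcm10, a replication factor (-2.09 ± 0.39). The median was -1.09 (camera adjusted p = 9.54e-18, adjusted p = 0.238 with an estimated correlation), and it was -0.84, -1.21, -1.34 and -0.96 in the 4 slides. Pbk, another mitotic kinase, was 6.83-fold lower (-2.77 ± 0.55). Cdc25b, a phosphatase that activates cyclin-dependent kinases, was 9.69-fold higher (3.28 ± 0.18).

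Genes of naive and quiescent T cells were higher in the same stimulated cells: 12 of 26 rose (12 when adjusted over the list alone), with a median of 0.39 (camera adjusted p = 4.78e-06, adjusted p = 0.254 with an estimated correlation). S1pr1, the receptor for exit from lymph nodes, rose by 2.25 ± 0.29, Pik3ip1, an inhibitor of PI3 kinase, by 1.80 ± 0.21 and Tsc22d3 (GILZ) by 1.34 ± 0.19. Of the effector and memory CD4 genes 15 of 30 rose (15 higher and 1 lower when adjusted over the list alone), with a median of 0.80, 0.75 with bounds (camera adjusted p = 7.46e-06, adjusted p = 0.394 with an estimated correlation) and Lgals3, galectin-3, at 2.25 ± 0.52. Of the interferon-stimulated genes 12 rose and 2 fell of 37 (13 and 2 when adjusted over the list alone), with a median of 0.48, 0.47 with bounds and 0.10 with a signal floor (camera adjusted p = 2.22e-04, adjusted p = 0.488 with an estimated correlation). Usp18, a protease for ISG15, rose by 2.75 ± 0.19 and Oas1a, an antiviral synthetase, by 1.90 ± 0.26. Of the inhibitory receptor and anergy genes 8 of 23 rose (8 higher and 1 lower when adjusted over the list alone), with Ndrg1 at 1.26 ± 0.16, Btla at 0.90 ± 0.18 and a median of 0.45, 0.42 with bounds (camera adjusted p = 0.00451, adjusted p = 0.238 with an estimated correlation). On the 4 slides the medians were 1.15, 0.06, 0.15 and 0.71 for interferon-stimulated genes, 0.51, 0.56, 0.43 and 0.51 for naive and quiescence, 0.88, 0.45, 0.53 and 0.95 for effector and memory and 0.30, 0.37, 0.64 and 0.31 for inhibitory receptor genes. B cell markers moved with these groups, with a median of 0.96, 0.04 with a signal floor (camera adjusted p = 0.00190, adjusted p = 0.537 with an estimated correlation), 4 of 16 members higher (4 when adjusted over the list alone) and Fcer2a (CD23) at 2.57 ± 0.55. Their median was 1.84, 0.95, 1.74 and 0.31 on the 4 slides. So did Epcam, an epithelial adhesion molecule (1.55 ± 0.26). Myeloid markers had a median of 0.88, 0.83 with bounds and 0.23 with a signal floor (camera adjusted p = 0.0726), with 1 of 21 at an unadjusted p under 0.05 and none called by limma, also adjusted over the list alone. Of the CD8, NK and unconventional T markers 3 rose and 1 fell of 14 (3 and 1 when adjusted over the list alone), with a median of 0.41, -0.28 with bounds and 0.00 with a signal floor (camera adjusted p = 0.403). Of the stromal and epithelial markers 1 of 4 rose (2 when adjusted over the list alone), with a median of 0.72, 0.35 with a signal floor (camera adjusted p = 0.0336, adjusted p = 0.254 with an estimated correlation), a call lost under several alternatives, among them after quantile normalization (adjusted p = 0.132) and without CKO replicate 4 (0.104).

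Ribosome biogenesis genes were lower in stimulated CKO cells too: 13 of 33 fell (21 when adjusted over the list alone), with Wdr12 at -0.75 ± 0.16 and a median of -0.42 (camera adjusted p = 9.81e-07, adjusted p = 0.394 with an estimated correlation), a call lost after normexp correction (adjusted p = 0.0557). It was -0.38, -0.46, -0.62 and -0.17 on the 4 slides. Rises outside the lists included M1ap, a meiosis gene, 28.3-fold (4.82 ± 0.26), Pgpep1l (4.59 ± 0.32) and Cyp2s1, a cytochrome, 9.51-fold (3.25 ± 0.25). Wfdc2 was at least 18.6-fold higher and F12 at least 11.5-fold higher. Spin4, a spindlin, was 9.21-fold lower (-3.20 ± 0.34), Eomes, a T-box factor of cytotoxic cells, 7.54-fold lower (-2.91 ± 0.61) and Ptger2, a prostaglandin receptor, 6.14-fold lower (-2.62 ± 0.25). Il2 differed by -0.13 ± 0.32, adjusted p = 0.803, Il2ra by -0.00 ± 0.16, adjusted p = 0.993 and Ifng by -0.33 ± 0.40, adjusted p = 0.573. Cd8a was not well above background on any WT stimulated array and was so on 2 of 4 CKO arrays, so it has no fold. Its values were higher in CKO (limma adjusted p = 0.0201), a call lost after quantile normalization (adjusted p = 0.0525), after normexp correction (0.675), with the authors' normalized values (0.0524), with the mean of kept probes (0.0666) and without WT replicate 3 (0.0586) or CKO replicate 2 (0.0619). Among effector cytokines 2 rose and 1 fell of 18 (2 and 1 when adjusted over the list alone) with camera adjusted p = 0.977, and among IL-2 and STAT5 targets 6 rose and 2 fell of 23 (7 and 3 when adjusted over the list alone) with camera adjusted p = 0.102. In the erythroid and platelet list limma called none of 7, none at an unadjusted p under 0.05 or adjusted over the list alone (camera adjusted p = 0.805).

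Between CKO and WT stimulated cells 3964 genes differed, 1912 higher and 2052 lower. The split depended on the scaling: 48.2% of called genes were higher, against 69.4% when arrays were scaled on the brightest shared probes, which moved the median of all genes by 0.16, and 60.8% after quantile normalization. The sign within each of the 4 slides matched the call for 97.9, 99.8, 99.6 and 93.3% of called genes, which were chosen on the same arrays. The count was 2385 without WT replicate 2, 2506 without CKO replicate 2 and 2452 without CKO replicate 3. It was 2382 after quantile normalization, 2412 after normexp correction, 2377 with the authors' normalized values, 2496 with no filter on dim probes and 8259 with array weights.

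In Treg without Trim28, Tdrd9 was 338-fold higher (8.40 ± 0.72), Cbr3 55.5-fold (5.79 ± 0.62) and Gstt3 34.4-fold (5.10 ± 0.28). Ube2e2, a ubiquitin-conjugating enzyme, was 24.7-fold higher (4.62 ± 0.24) and Ak7, an adenylate kinase of motile cilia, 16.9-fold (4.08 ± 0.19). A second Ube2e2 probe, not used for the gene, gave a smaller log2 fold change of 1.72. Upk1b was at least 201-fold higher and the amino acid transporter Slc1a4 at least 52.1-fold higher. Plagl1, an imprinted zinc finger gene, was 17.3-fold lower (-4.11 ± 0.28) and Rnf43 7.92-fold lower (-2.99 ± 0.27). Penk, which encodes proenkephalin, was 4.98-fold lower (-2.32 ± 0.51) and Areg, amphiregulin, 4.21-fold lower (-2.07 ± 0.37). Rora, a nuclear receptor of the Th17 program, fell (-1.51 ± 0.22).

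KRAB zinc finger genes, whose products recruit TRIM28, were higher in CKO Treg: 16 rose and 1 fell of 102 (25 and 3 when adjusted over the list alone), with Zfp948 at 2.61 ± 0.32, Zfp458 at 2.16 ± 0.25 and Zfp936 at 1.65 ± 0.24. The median was 0.31, 0.33 with bounds and 0.16 with a signal floor (camera adjusted p = 6.11e-09, adjusted p = 0.0374 with an estimated correlation), and it was 0.40, 0.20, 0.15 and 0.27 in the 4 slides. Partners of TRIM28 rose, 3 of 28 measured (3 when adjusted over the list alone): Setdb1, the histone methyltransferase that TRIM28 recruits (2.44 ± 0.21), Trim24 (3.23 ± 0.14) and Morc3, a chromatin ATPase (2.06 ± 0.13). That list's call (camera adjusted p = 0.0498, adjusted p = 0.571 with an estimated correlation) was lost under several alternatives, among them leaving out any of WT replicates 1, 3 and 4 (adjusted p = 0.0562, 0.0802 and 0.0700) or CKO replicates 2 and 4 (0.0936 and 0.0718). Ribosome biogenesis genes had a median of -0.30 (camera adjusted p = 6.11e-09, adjusted p = 0.571 with an estimated correlation) with 3 of 33 lower (8 when adjusted over the list alone): Noc2l (-0.47 ± 0.12), Heatr1 (-0.46 ± 0.11) and Utp20 (-0.45 ± 0.12). Each of the 3 lost its call with only the Treg arrays fitted (adjusted p = 0.305, 0.265 and 0.258), without WT replicate 1 (adjusted p = 0.124, 0.0736 and 0.115) and without CKO replicate 2 (0.0944, 0.0696 and 0.0728). With the mean of kept probes Heatr1 was at -0.26 (adjusted p = 0.538) and Utp20 at -0.10 (0.903). The cholesterol synthesis list had a median of -0.41 (camera adjusted p = 9.43e-06, adjusted p = 0.571 with an estimated correlation). Of its members 1 rose and 1 fell of 22 (1 and 3 when adjusted over the list alone), and 12 were lower at an unadjusted p under 0.05. On the 4 slides the medians were -0.35, -0.36, -0.34 and -0.15 for ribosome biogenesis, -0.47, -0.59, -0.47 and -0.09 for cholesterol synthesis and 0.15, 0.06, -0.02 and 0.09 for the partners of TRIM28. Of the other cell types' markers, B cells had a median of 0.23, 0.26 with bounds and 0.14 with a signal floor (camera adjusted p = 0.255), with 1 of 16 at an unadjusted p under 0.05 and none called by limma, and Epcam rose (1.83 ± 0.26). Of the CD8, NK and unconventional T markers 2 rose and 1 fell of 14 (2 and 1 when adjusted over the list alone), with a median of 0.53, 0.51 with bounds and 0.00 with a signal floor (camera adjusted p = 0.255) and 1.33, 0.41, 0.33 and -0.01 in the 4 slides. Klrb1c (NK1.1) rose (1.99 ± 0.46), a call lost without WT replicate 3 (adjusted p = 0.0538), without CKO replicate 1 (0.0504), with only the Treg arrays fitted (0.0516) and after normexp correction (0.0612).

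The Treg signature in CKO Treg had 5 of 22 members lower (6 lower and 1 higher when adjusted over the list alone), among them Plagl1 and Gpr83 (-1.42 ± 0.20). Its median was 0.01 while its mean was -0.45 and the test read down (camera adjusted p = 0.0294, adjusted p = 0.635 with an estimated correlation). The call was lost under several alternatives, among them after quantile normalization (adjusted p = 0.160), among genes well above background on all 24 arrays (0.856) and without WT replicate 1 (0.0562), WT replicate 4 (0.0705) or CKO replicate 2 (0.0532). Ifng, the main cytokine of Th1 cells, was 3.11-fold lower (-1.64 ± 0.40, adjusted p = 0.0184), and its adjusted p was 0.0650 without WT replicate 4, 0.0535 without CKO replicate 2 and 0.0504 without CKO replicate 3. Il2ra differed by -0.12 ± 0.16, adjusted p = 0.834. The treatment tag of the labels calls CKO Treg TCR-stimulated and WT Treg unstimulated, while the design text gives stimulation for naive cells only. T cell activation genes had a median of -0.12, -0.04 with a signal floor in this comparison (camera adjusted p = 0.543, adjusted p = 0.923 with an estimated correlation), and 1 of 25, Myc, was lower (-0.61 ± 0.15), also when adjusted over the list alone. Myc lost its call under several alternatives, among them with only the Treg arrays fitted (adjusted p = 0.0823) and without WT replicate 1 (0.0540), WT replicate 3 (0.0519) or CKO replicate 3 (0.0791). Of 12 germline genes 1, Tdrd9, rose (1 when adjusted over the list alone), with a median of 0.37, 0.51 with bounds and 0.00 with a signal floor (camera adjusted p = 0.146).

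Between CKO and WT Treg 710 genes differed, 407 higher and 303 lower (57.3% higher, against 47.5% after quantile normalization). The sign within each of the 4 slides matched the call for 99.7, 99.4, 99.9 and 99.0% of called genes, again chosen on the same arrays. The count was 365 with only the 8 Treg arrays fitted, 472 among genes well above background on all 24 arrays and 574 without the dimmest array of each Treg group. Other normalizations raised it. Quantile normalization gave 488 higher and 539 lower, normexp correction 506 and 480, and the authors' normalized values 487 and 531.

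**Figure D2:**
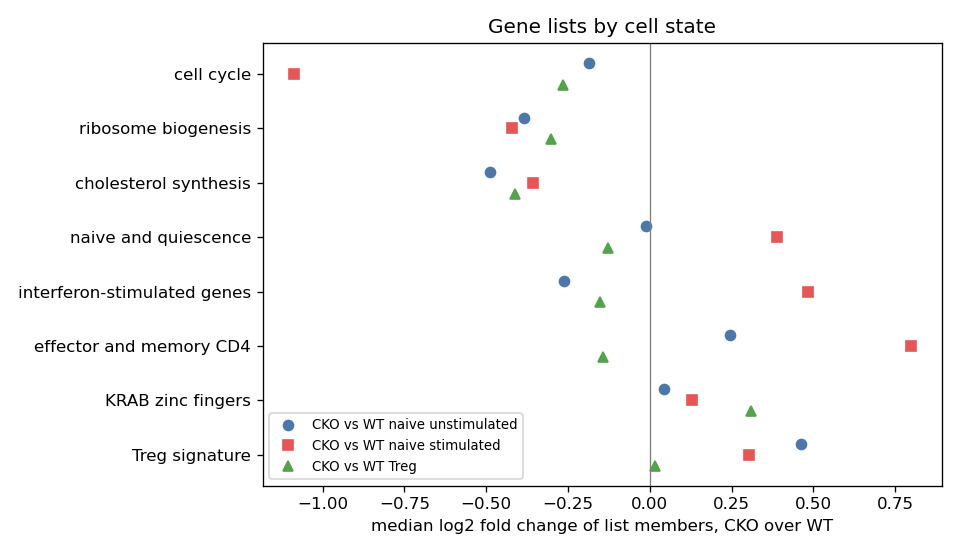
Median log2 fold change, CKO against WT, of 8 gene lists in naive unstimulated, naive stimulated and Treg cells. Cell cycle genes lie lowest in stimulated cells and KRAB zinc finger genes highest in Treg.

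The genotype differences correlated between states. Across genes, which are not independent replicates, Pearson's r was 0.582 between unstimulated and stimulated naive cells (Spearman's rho 0.568), 0.515 between unstimulated naive cells and Treg (0.408) and 0.330 between stimulated naive cells and Treg (0.201). With no filter on dim probes the first and last fell to 0.452 and 0.122. In unstimulated and stimulated cells 554 genes were higher in both (149.7 expected if the calls were independent) and 696 lower (224). In unstimulated cells and Treg 244 genes were higher in both (31.9 expected if the calls were independent) and 174 lower (33.0). In stimulated cells and Treg 202 genes were higher in both (47.2 expected if the calls were independent) and 124 lower (37.7). In all 3 states 155 genes were higher (3.70 expected) and 92 lower (4.11).

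Stimulation raised ribosome biogenesis in both genotypes: 33 of 33 genes rose in WT (median 2.24, camera adjusted p = 4.17e-17, adjusted p = 0.243 with an estimated correlation) and 33 in CKO (median 2.31, camera adjusted p = 1.92e-19, adjusted p = 0.162 with an estimated correlation), with 33 and 33 when adjusted over the list alone. Il2ra rose 211-fold in WT (7.72 ± 0.16) and 98.2-fold in CKO (6.62 ± 0.16), and Tnfrsf9, the costimulatory receptor 4-1BB, 59.0-fold and 44.2-fold. Il2 rose 25.8-fold in WT (4.69 ± 0.32) and was at least 30.4-fold higher in CKO. The interaction term for Il2 did not pass (limma adjusted p = 0.427), so the larger CKO value does not show a stronger response. Cell cycle genes rose in number, 33 of 41 in WT with 4 lower (33 and 4 when adjusted over the list alone) while 23 rose in CKO with 5 lower (24 and 5). Their medians were 1.90 (camera adjusted p = 1.41e-08, adjusted p = 0.395 with an estimated correlation) and 1.05, 0.31 with a signal floor (camera adjusted p = 1.55e-04, adjusted p = 0.430 with an estimated correlation). Of the T cell activation genes 14 rose and 6 fell of 25 (14 and 6 when adjusted over the list alone) in WT (camera adjusted p = 0.00778, adjusted p = 0.395 with an estimated correlation).

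Interferon-stimulated genes fell on stimulation, 32 of 37 in WT (33 when adjusted over the list alone, median -3.20, -2.48 with bounds and -1.87 with a signal floor, camera adjusted p = 6.98e-13, adjusted p = 0.243 with an estimated correlation). In CKO 30 fell (30 when adjusted over the list alone, median -2.11, camera adjusted p = 4.72e-10, adjusted p = 0.430 with an estimated correlation). Of the naive and quiescence genes 4 rose and 19 fell of 26 (4 and 20 when adjusted over the list alone) in WT (camera adjusted p = 1.23e-07, adjusted p = 0.243 with an estimated correlation). In CKO 4 rose and 20 fell of 26 (4 and 21 when adjusted over the list alone) (camera adjusted p = 1.27e-05, adjusted p = 0.430 with an estimated correlation). Cxcr4, a homing receptor, was 132-fold lower in WT (-7.05 ± 0.26) and 47.7-fold lower in CKO (-5.58 ± 0.26). Tgfb3 was 14.4-fold lower in WT, where only 2 of 4 stimulated arrays were well above background, and 13.0-fold lower in CKO. Trim28 rose 2.30-fold in WT (adjusted p = 2.40e-06) and differed by 0.03 ± 0.17, adjusted p = 0.889 in CKO. Markers of other cells fell with these groups: 15 of 16 B cell markers in WT and 15 in CKO (15 and 15 when adjusted over the list alone), with medians with bounds of -2.93 in WT (camera adjusted p = 1.13e-04, adjusted p = 0.395 with an estimated correlation) and -2.86 in CKO (camera adjusted p = 1.01e-04, adjusted p = 0.430 with an estimated correlation). With a signal floor the WT median was -1.62. Of 21 myeloid markers 19 fell in WT and 16 in CKO (20 and 16 when adjusted over the list alone). Of the CD8, NK and unconventional T markers 1 rose and 11 fell of 14 (1 and 11 when adjusted over the list alone) in WT (median -2.77, -1.38 with bounds and -0.17 with a signal floor, camera adjusted p = 0.00168, adjusted p = 0.395 with an estimated correlation), a call lost with a signal floor (adjusted p = 0.172). In CKO 1 rose and 13 fell of 14 (1 and 13 when adjusted over the list alone) (median -3.13, -2.82 with bounds and -1.29 with a signal floor, camera adjusted p = 1.55e-04, adjusted p = 0.430 with an estimated correlation).

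In WT 10202 genes changed on stimulation, 5222 higher and 4980 lower. In CKO 9922 did, 4904 higher and 5018 lower. Scaling on the brightest shared probes moved the median of all genes by -0.25 in WT and -0.17 in CKO. By this scaling 40.1% and 40.8% of called genes were higher, against 51.2% and 49.4%. The 2 responses correlated across genes with r = 0.917 (rho 0.907), although genes are not independent replicates, and 4323 genes were higher in both and 4086 lower. Within the 2 slides that held both states of a genotype, the sign matched the call for 98.3 and 99.9% of genes in WT and 99.8 and 99.6% in CKO. The called genes had been chosen on arrays that include these, so such agreement is largely built in.

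The response to stimulation differed between genotypes for 564 genes by the interaction term, 350 with a higher and 214 with a lower response in CKO. Naive and quiescence genes had a higher response in 11 of 26 members (13 when adjusted over the list alone, median 0.57, camera adjusted p = 2.38e-10, adjusted p = 0.104 with an estimated correlation), among them S1pr1 (2.26 ± 0.41) and Il7r, the IL-7 receptor (2.07 ± 0.43). Interferon-stimulated genes did so in 5 of 37 (13 higher and 1 lower when adjusted over the list alone, median 0.65, 0.63 with bounds, camera adjusted p = 3.67e-10, adjusted p = 0.262 with an estimated correlation), with Usp18 at 2.50 ± 0.27. Cell cycle genes had a lower response in 10 of 41 (20 when adjusted over the list alone, median -0.88, -0.92 with bounds, camera adjusted p = 8.70e-16, adjusted p = 0.216 with an estimated correlation), such as Gins1, part of the replicative helicase (-1.53 ± 0.21), and Ccne1, cyclin E1 (-1.34 ± 0.29). Of the chromatin partners of TRIM28 3 of 28 were lower (6 lower and 2 higher when adjusted over the list alone, median -0.37, camera adjusted p = 1.07e-04, adjusted p = 0.104 with an estimated correlation), with Trim24 at -2.03 ± 0.19 and Morc3 at -1.28 ± 0.18.

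Large interactions among single genes were upward for Cdc25b (3.03 ± 0.26) and Pde2a, a phosphodiesterase (2.94 ± 0.27), and downward for Ak7 (-4.18 ± 0.27) and B4galt4 (-3.59 ± 0.32). For Trim28 it was -1.17 ± 0.24, adjusted p = 0.00756. For Foxp3 it was 1.49 ± 0.28, adjusted p = 0.00460, with the call lost after normexp correction (adjusted p = 0.0995). It was also lost with a signal floor, at 0.60 (adjusted p = 0.139). That floor lies above Foxp3 on every WT stimulated array, so the size of this interaction rests on low signals. For Il2ra it was -1.10 ± 0.23, adjusted p = 0.00815, with the sign turned after normexp correction, at 0.04, and the call lost after quantile normalization (adjusted p = 0.139) and with the authors' normalized values (0.139). B cell markers did not pass (median 0.05, -0.39 with a signal floor, camera adjusted p = 0.989), with none of 16 at an unadjusted p under 0.05 in limma. CD8, NK and unconventional T markers had a median of -0.82, -1.40 with bounds (camera adjusted p = 0.119), with 4 of 14 lower and 1 higher at an unadjusted p under 0.05, none called by limma over all genes and 3 lower when adjusted over the list alone. The count of 564 was 372 without CKO unstimulated replicate 2, 360 without CKO stimulated replicate 1, 297 with no filter on dim probes, 865 with a signal floor and 2756 with array weights.

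Treg expressed more of their signature genes than naive unstimulated cells did. Foxp3 was 65.6-fold higher in WT (6.04 ± 0.20) and 35.8-fold in CKO (5.16 ± 0.20). Il2ra was 164-fold (7.35 ± 0.16) and 70.1-fold (6.13 ± 0.16) higher, Socs2, a suppressor of cytokine signalling, 82.4-fold and 42.7-fold and Itgae (CD103) 58.1-fold and 36.0-fold. Itgb8, an integrin chain that activates latent TGF-beta, was at least 27.4-fold higher in WT and at least 11.5-fold higher in CKO. Of the Treg signature 22 of 22 rose in WT and 19 in CKO (22 and 19 when adjusted over the list alone), with medians of 3.73 and 3.09. The camera adjusted p was 1.92e-26 and 9.04e-29, and both calls held with an estimated correlation (adjusted p = 8.64e-04 and 5.23e-04). Of the inhibitory receptor and anergy genes 15 rose and 4 fell of 23 (15 and 4 when adjusted over the list alone) in WT (camera adjusted p = 2.81e-04, adjusted p = 0.0249 with an estimated correlation). Ctla4 rose 28.7-fold there (4.85 ± 0.28).

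Genes lower in Treg included Ggt5, a gamma-glutamyl transferase, 48.1-fold in WT (-5.59 ± 0.16) and 29.8-fold in CKO (-4.90 ± 0.16), Pde3b, a phosphodiesterase, 17.2-fold and 19.5-fold, and Klrd1 (CD94), 18.6-fold and 15.0-fold. Tgfb3 was 2.12-fold lower in WT Treg (-1.08 ± 0.29) and 2.31-fold lower in CKO Treg (-1.21 ± 0.29). Ribosome biogenesis genes were lower, 20 of 33 in WT, where 1 was higher, and 13 in CKO (21 and 13 when adjusted over the list alone), with medians of -0.55 in WT (camera adjusted p = 2.81e-04, adjusted p = 0.707 with an estimated correlation) and -0.36 in CKO (camera adjusted p = 3.98e-04, adjusted p = 0.615 with an estimated correlation). Markers of other cells were lower too. In WT 8 of 16 B cell markers fell (12 when adjusted over the list alone, median -1.56, -1.46 with bounds and -0.88 with a signal floor, camera adjusted p = 0.0215, adjusted p = 0.707 with an estimated correlation), a call lost without WT unstimulated replicate 2 (adjusted p = 0.0537), without WT Treg replicate 1 (0.0594), with a signal floor (0.130) and among genes well above background on all 24 arrays (0.426). The same markers were lower in CKO, with 14 of 16 members called (14 when adjusted over the list alone, median -2.55, -2.25 with bounds, camera adjusted p = 7.32e-06, adjusted p = 0.615 with an estimated correlation), a call lost among genes well above background on all 24 arrays (adjusted p = 0.0507). Of the CD8, NK and unconventional T markers 10 of 14 were lower and 1 higher in CKO (10 and 1 when adjusted over the list alone, median -2.26, -1.48 with bounds and -1.38 with a signal floor, camera adjusted p = 6.51e-04, adjusted p = 0.615 with an estimated correlation). In WT 7974 genes differed, 3119 higher and 4855 lower. In CKO 4666 differed, 1910 higher and 2756 lower, or 11679 with no filter on dim probes. Scaling on the brightest shared probes moved the median of all genes by 0.23 in WT and 0.15 in CKO. The share of called genes that were higher went from 39.1% to 60.7% and from 40.9% to 58.3%. Across genes, which are not independent replicates, the differences in WT and CKO correlated with r = 0.773 (rho 0.751). Within the 2 slides that held both cell types of a genotype the sign matched for 99.6 and 97.2% and 99.6 and 99.5% of called genes. That agreement too is largely built in, because the calls used these arrays.

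The genotype difference itself differed between Treg and naive unstimulated cells for 65 genes by the interaction term, 39 upward in Treg and 26 downward. Setdb1 was upward (2.61 ± 0.29), with Acadm, a mitochondrial dehydrogenase of fatty acids, at 1.65 ± 0.22 and Prnp, the prion protein, at 1.65 ± 0.27. Cybrd1, an iron reductase (-3.64 ± 0.31), Plagl1 (-3.13 ± 0.40) and Rora (-1.87 ± 0.31) were downward. Il2ra was at -1.22 ± 0.23, adjusted p = 0.00998, with the call lost after normexp correction (adjusted p = 0.430) and with only the compared arrays fitted (0.0545). Of the Treg signature 3 of 22 were downward (7 lower and 1 higher when adjusted over the list alone, median -0.67, -0.34 with a signal floor, camera adjusted p = 3.57e-06, adjusted p = 0.215 with an estimated correlation). The Th17 program had 1 of 14 downward (2 when adjusted over the list alone, camera adjusted p = 0.0124, adjusted p = 0.311 with an estimated correlation). The stromal and epithelial list did not pass (camera adjusted p = 0.166), with none of 4 members at an unadjusted p under 0.05 in limma. B cell markers had a median of -0.95 (camera adjusted p = 0.0125, adjusted p = 0.869 with an estimated correlation), with 1 of 16 lower at an unadjusted p under 0.05 and none called by limma, also adjusted over the list alone. That call was lost without WT unstimulated replicate 1 (adjusted p = 0.175), CKO unstimulated replicates 1 and 2 (0.0740 and 0.133), WT Treg replicate 2 (0.138) or CKO Treg replicate 4 (0.177), and among genes well above background on all 24 arrays (0.178). CD8, NK and unconventional T markers had a median of -0.52 (camera adjusted p = 0.0514), with none called by limma over all genes, 3 of 14 lower and 1 higher at an unadjusted p under 0.05 (2 and 1 when adjusted over the list alone). The count was 358 without WT unstimulated replicate 4, 102 after quantile normalization, 183 after normexp correction and 101 with the authors' normalized values. It was 101 with replicate number as a block, 104 with slide as a random block, 246 with a signal floor, 1025 with array weights and 23 among genes well above background on all 24 arrays. The share upward was 60%, or 50% when scaled on the brightest shared probes.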

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

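The tests on Foxp3 in this part were chosen only after its values had been seen, as were the alternatives on dim Treg arrays and bright genes and the ratios with arrays left out. Of 90 sets of 4 arrays tested, each for 1 gene, 1 list or 1 measure of array signal, 5 had 1 array far from the other 3, and chance gives about 1 in 20. All 5 were for a gene or list. CKO unstimulated replicate 3 had a log2 value of 2.62 for Tgfb3 (others 2.05 to 2.14), and CKO stimulated replicate 3 had -1.74 for Tgfb3 (others -1.40 to -1.35). For Cd4, WT stimulated replicate 1 had -1.19 (others -0.84 to -0.81) and WT Treg replicate 1 had -0.76 (others -0.34 to -0.30). For the mean of CD8, NK and unconventional T markers, WT Treg replicate 3 had -3.72 (others -3.05 to -2.94).

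The effect of the genotype differed between stimulated and unstimulated cells by an interaction test for 564 genes, among them Trim28 (-1.17), Foxp3 (1.49) and Il2ra (-1.10). It differed between Treg and unstimulated naive cells for 65 genes, among them Il2ra (-1.22). For each interaction 4 of the 100 drawn splits of the 16 arrays gave as many genes, the real one included. Redrawing the genotype labels within a state also breaks up the genotype effect of that state. The splits are therefore no clean set without an interaction, and they cannot exclude chance. The highest of the other splits gave 4803 and 462 genes, more than the real counts. In genotype by stimulation that split had exchanged every genotype label in stimulated cells and kept 3 of 4 in unstimulated cells, so it largely turned the genotype effect of 1 state around. In genotype by cell type it kept 3 of 4 in unstimulated cells and 2 of 4 in Treg, and its count has no explanation here.

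For the 7 comparisons of groups, the real split gave more genes than any of the other splits of the same 8 arrays, so 1 of 35 was as large. That is the smallest share these splits can give, so a chance split is made unlikely for each comparison but is not excluded. Splits that mix the groups count the group difference as spread, so the margins over them are partly built in. The real counts and the highest of the other splits were 3088 against 1287 (CKO and WT unstimulated), 3964 against 50 (stimulated), 710 against 142 (Treg), 10202 against 382 (stimulation in WT), 9922 against 1 (in CKO), 7974 against 4197 (Treg and naive in WT) and 4666 against 1 (in CKO).

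Fewer genes differed between CKO and WT in Treg (710) than in unstimulated naive cells (3088), a ratio of 0.230. Single arrays of unstimulated cells move it: it was 0.513 without WT replicate 2, 0.446 without WT replicate 3, 0.440 without CKO replicate 2 and 0.422 without CKO replicate 3, and under 1 whichever array was left out. Normalization moves it too. After quantile normalization 488 genes were higher and 539 lower in Treg, against 1278 and 1733 in unstimulated cells. Treg arrays were dimmer, and dim arrays could hide changes. The tables argue against this as the whole cause: among the 11118 genes well above background on all 24 arrays the ratio was 0.169, no nearer to 1, and 0.132 to 0.373 with 1 array left out at a time. Smaller genotype effects in Treg remain as a candidate explanation. Over the 3028 such genes called in stimulated cells, signed by that effect, the median effect was 0.08 in Treg and 0.35 in unstimulated cells, a difference of -0.27 (95% interval over genes -0.29 to -0.25). The genes were chosen in a naive state, so this test cannot separate a weaker effect from a different one. The treatment tag calls CKO Treg stimulated, and the values argue against a response like that of naive cells. Stimulation moved ribosome biogenesis genes by a median of 2.31 in CKO naive cells. In CKO against WT Treg their median was -0.30, and -0.35, -0.36, -0.34 and -0.15 on the slides. T cell activation genes had medians of 0.90 and -0.12 in these comparisons. Treg of known stimulation were not measured, so another kind of response in Treg stays open.

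Foxp3 was higher in CKO naive cells. A larger share of Treg among the sorted cells is a candidate explanation, although the CD25- gate of the sort selects against them. Foxp3 itself would need 1.37% more Treg in unstimulated cells. The 13 other Treg marker genes gave a median of 1.01% (95% interval over genes 0.551 to 1.67), near that share, with a range from -0.265 to 5.91. Several of them, such as 4732457N14, Fam160a1 and Itgb8, were not well above background on any WT unstimulated array. The median is the value of 4732457N14, so it rests partly on background signal and cannot decide the question. In stimulated cells Foxp3 would need 3.28%, and 13 Treg markers that stimulation of WT cells did not change, in part other genes, gave a median of 1.12% (0.510 to 1.99), with a range over markers from -0.461 to 26.9, so added Treg and raised Foxp3 in naive cells cannot be told apart. Loss of Trim28 acting on Foxp3 was not tested.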

How the results depend on the processing

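The alternatives without the dimmest Treg arrays and with bright genes alone were chosen after seeing the data. Trim28 kept its direction and its call in all 3 states under every alternative run, and no called list reversed. Counts that moved by over 1.5 times follow, and the cause was not tested. For CKO against WT stimulated cells the count of 3964 was 2382 after quantile normalization, 2412 after normexp correction, 2377 with the authors' values and 2496 with no filter on dim probes. That filter's absence also gave 1801 for unstimulated cells, 297 for genotype by stimulation, 11679 for Treg against naive CKO cells and correlations of 0.452 (2 naive states) and 0.122 (stimulated and Treg). With only the compared arrays the counts were 1700 in unstimulated cells and 365 in Treg. Array weights gave 6616, 8259, 2756 and 1025 for unstimulated, stimulated, genotype by stimulation and genotype by cell type. In that fit CKO stimulated replicate 2 had a weight of 8.96, against 1.87, 0.60 and 0.41 for the other arrays of its group. The means of that group, and the counts that use them, therefore lean on 1 array. A signal floor gave 865 and 246 for the interactions. That floor, a log2 value of -2.69, lies above Il2ra on every unstimulated array, so it cannot test Il2ra there. Genotype by cell type, 65 genes, had 102 after quantile normalization, 183 after normexp correction, 101 with the authors' values, 101 with a replicate block, 104 with slide as a random block and 23 among bright genes, which also gave 472 in Treg, where fewer genes were tested.

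Leaving out 1 array at a time gave 1385 to 4591 genes for unstimulated, 2385 to 4669 for stimulated and 576 to 707 for Treg CKO against WT, 9698 to 10049 and 9198 to 9813 for stimulation in WT and CKO, 360 to 772 for genotype by stimulation, 6379 to 8461 and 3283 to 4944 for Treg against naive in WT and CKO, and 52 to 358 for genotype by cell type. Trim28 ran from -1.63 to -1.39, -2.77 to -2.54 and -1.65 to -1.49 in the 3 states, and the correlations from 0.524 to 0.626, 0.411 to 0.561 and 0.237 to 0.430. A block on slide gave 3507, 4470 and 823 genes for CKO against WT as a fixed term, and a block on replicate number 3818, 4891 and 911, with 10574 and 10373 for stimulation, 742 for its interaction and 8638 for Treg against naive WT cells. Without the dimmest array of each Treg group the counts were 574 in Treg, 6872 and 5015 for Treg against naive and 70 for genotype by cell type.

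The values of 6 genes reversed. Il2ra in genotype by stimulation was 0.0354 after normexp correction. With the mean of kept probes Klf13 was 0.26, Pfkfb3 0.18 and Gnas 0.0188 in unstimulated cells, Rrp15 0.13 in Treg against naive WT cells and Fdft1 -0.20 in CKO cells. None of the other named genes reversed. All arrays were scanned on 1 day, so an alternative by scan date was not run.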

Other observations

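Genes that were at least 2-fold higher in CKO than in WT unstimulated cells, here called raised, lay beside each other on the chromosomes more often than permuted genes: 41 adjacent pairs were seen against a mean of 11.4 over 10000 permutations. Probes shared between related genes may explain part of it. With pairs of the same symbol stem left out, 27 pairs stood against 10.7 (permutation p = 1e-04, the smallest these permutations can give). A clustering of any changed genes is another candidate explanation: genes at least 2-fold lower gave a factor of 2.31 against 3.61 for raised ones. Both tests are void, because positions could be given to 58.4% of the 656 raised genes and 77.0% of the lowered ones, under the 80% that had been required, so neither explanation can be settled here.

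A second Cd4 probe, dimmer and not used for the gene, was noted after its values were seen. It read -0.32 ± 0.73 (SD, n = 4) in WT and -1.64 ± 0.45 in CKO unstimulated cells, -1.33 ± 0.86 and -2.05 ± 0.43 in stimulated cells and -1.70 ± 0.19 and -1.93 ± 0.24 in Treg.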
